A study of Homo sapiens with 18 samples.

How the data were processed

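RNA was sequenced from HUDEP-2, an established human erythroid progenitor line derived from umbilical cord blood that makes mainly adult globin, and from HUDEP-2 cells whose HBB gene was disrupted (HBBko). Per the labels, both lines were cultured and differentiated in triplicates, total RNA was extracted with an RNeasy kit and made into TruSeq libraries. The 18 libraries form 6 groups of 3: unedited cells (WT) and HBBko cells, each undifferentiated, after 48 h and after 5 d of differentiation. The labels do not say whether the triplicates of a group were started independently of each other. They also do not say how many clones the HBBko line came from, or when each library was made.

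The submitters' processing notes name hg38, kallisto and sleuth, without versions or the transcript annotation used. The authors deposited a table of signal per gene symbol that its name calls TPM, and the library sums of that signal run from 783213 to 1508340, so it is TPM that had also been scaled between libraries in a step that the notes do not state. It is called scaled TPM here. The plan written beforehand took the table for plain TPM, and the test was kept unchanged. The columns of that table carry the stage and the replicate number, but name the lines only as thal and wen. The columns named thal were read as HBBko, from thalassaemia, the disease of beta-globin loss, and wen as WT. This reading rests on the names alone, and HBB was lower in every thal library than in any wen library of the same stage. The authors also deposited 3 tables, 1 per stage, that give per gene a log2 fold change with its standard error. Per the file headers, the same deposited tables hold a p value and a q value for each gene, in the layout of sleuth's output. Counts of reads are not in the files used here, so the depth of each library is unknown and no counting interval can be given. The precision comes from the spread between replicate libraries alone. For a log2 fold change fitted here, the standard error pools that spread over the 6 groups. It therefore does not reflect the spread of the groups compared alone.

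The table lists 35616 genes, of which 25969 were above 0 in at least 1 library. Genes with at least 1 scaled TPM in at least 3 libraries were tested (12005 genes). Values were taken as log2(scaled TPM + 1) with no further scaling and fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), all 18 libraries in 1 fit with a mean per group, which left 12 residual degrees of freedom. A log2 fold change is therefore a difference of means of log2(scaled TPM + 1), pulled toward 0 for genes near 1 scaled TPM. Tests were two-sided and p values were adjusted by Benjamini and Hochberg over all tested genes. A gene counted as called at an adjusted p under 0.05, and a second count asked in addition for a log2 fold change of at least 1 in size. There were 10 comparisons: HBBko against WT at each of the 3 stages, 48 h and 5 d against undifferentiated in each line, and 3 interactions, each the difference between the HBBko against WT changes at 2 stages. Means are given with the standard deviation (SD) and log2 fold changes with the standard error (SE) of the fit. Globin shares were computed per library and compared by a two-sided exact permutation test, adjusted over the 21 shares, ratios and sums computed; with 3 libraries against 3 its smallest possible p is 0.1.

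The 30 gene lists, the comparisons, the rule for naming genes and all but 1 of the alternatives were fixed before the data were examined. The lists cover globins, globin regulators, ATF4 and amino acid response targets, eIF2alpha kinases and phosphatase, ER chaperones and the unfolded protein response, heat shock and cytosolic chaperones, the oxidative stress response, heme synthesis and transport, iron uptake and handling, red cell membrane and skeleton, late erythroid maturation, early progenitor genes, G2 and M phase, S phase and replication, cell cycle arrest and p53 targets, the proteasome, autophagy and mitophagy, cholesterol synthesis, glycolysis and the hypoxia response, the mitochondrial respiratory chain, ribosomal proteins, the interferon response, core histones, nuclear condensation and chromatin, the fetal and neonatal programme, and markers of myeloid, megakaryocyte, mast cell with basophil and eosinophil, lymphoid, and stromal and endothelial cells. All 673 symbols of the lists were found in the table, 23 of them under an older symbol through the gene identifier. No lymphoid marker passed the filter on low values. Each list was tested with limma's camera, which compares the list with all other tested genes, at its preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, which tests the list alone. Camera p values were adjusted over the lists within a comparison. Counts of called members are given over all tested genes and adjusted over the list alone.

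Named genes follow a fixed rule. HBB, HBG1, HBG2, HBA1, HBA2, HBD, HBE1, ATF4, MYB, BCL11A, KLF1 and EIF2AK1 were named in every HBBko against WT comparison whatever their result. Each such comparison added the 10 largest and the 10 smallest log2 fold changes among called genes with a mean of at least 5 scaled TPM in 1 of the 2 groups and no overlap between the 3 and 3 libraries, which chance alone gives in 1 of 10 splits of 6 libraries. Differentiation comparisons and interactions added 5 and 5 by the same rule. From each list described came up to 4 called members with the largest change in size or, where none was called, up to 2 with the highest mean. Unnamed transcripts and pseudogenes were given as counts or left out, except HBBP1, which lies in the beta-globin cluster. Coordinates are those of GENCODE version 29 on GRCh38, found for 11847 of the tested genes. HBG1 with HBG2, HBA1 with HBA2, HSPA1A with HSPA1B, TPSAB1 with TPSB2, and the metallothionein genes have near-identical sequences, and the annotated spans of HBD with HBBP1, of HBG2 with HBE1 and of HBZ with HBM overlap, so how the authors' quantification divided reads within each set is uncertain.

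Alternatives changed 1 choice at a time: a pseudocount of 0.1 or of 5; no filter, or a filter at 5; median-of-ratios scaling (library factors 0.891 to 1.15); globin genes removed and the rest rescaled; quantile normalization; a block on the replicate number; library weights; a fit of only the groups compared; each library left out in turn; for lists, fry and the estimated correlation; and for the gamma-globin share, HBG2 or HBG1 alone and a denominator of HBB, HBG1 and HBG2. Rescaling every library to equal sums was added after the data were seen. The replicate number pairs libraries in part: correlations of the same number across genes, after centring each group, were 0.173, 0.121 and 0.151 between the lines when undifferentiated, 0.133, 0.180 and 0.131 at 5 d, and 0.181, 0.102 and 0.194 between undifferentiated and 48 h WT cells, each above every correlation of different numbers in that pair of groups. At 48 h the same-number correlations between the lines were -0.0301, -0.0111 and 0.0219, between undifferentiated and 5 d HBBko cells they were 0.0670, 0.0819 and 0.0159, above those of different numbers but small, and 2 other pairs of groups showed no clear pairing, so the block was kept as an alternative.

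The procedure was tested on simulated data with 200 changed genes per comparison. It called 98.5% to 100% of 4-fold changes, 79.1% to 98.5% of 2-fold changes and 61.2% to 91.0% of 1.5-fold changes, with at most 14 unchanged genes called. A shifted list was called in all 10 comparisons and no unchanged list was. The simulated noise was independent between genes and had the same spread in every group. The simulation therefore cannot show how often camera wrongly calls lists of correlated genes. It also cannot show how unequal spread between groups affects gene calls. The authors' tables were set beside the fit without a new test. Splicing and single transcripts were not analysed here.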

Results

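RNA-seq libraries of the HUDEP-2 erythroid line were compared between unedited cells (WT) and cells with a disrupted HBB gene (HBBko), undifferentiated and after 48 h and 5 d of differentiation, with 3 libraries in each of the 6 groups. Values are in scaled TPM, and the number of reads behind them is unknown. Between 10410 and 11294 genes had at least 1 scaled TPM in a library. The first principal component of the 12005 tested genes held 76.2% of the variance and the second 13.4%. Within a group, correlations between libraries across genes (genes are not independent replicates) were 0.995 to 0.998, except among undifferentiated WT libraries, where they were 0.987 to 0.993. Replicate 3 of that group stood apart, with 22376 scaled TPM of HBB against 12517 and 12454 and 704 scaled TPM of ATF4 against 514 and 516. Replicate 3 of WT at 48 h also held more HBB (132741 scaled TPM) than the other libraries of its group (99196 and 103106). Mitochondrially encoded transcripts took 9.75% to 11.4% of the total in undifferentiated libraries. At 48 h they took 5.04% to 5.72% in WT and 7.18% to 7.79% in HBBko, and at 5 d 1.34% to 1.46% in WT and 2.29% to 2.97% in HBBko.

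The comparison of undifferentiated HBBko with WT cells asks what the loss of beta-globin changes before differentiation is induced, and the series title points to ATF4, MYB and gamma-globin. HBB (chromosome 11, 5225464 to 5229395, minus strand, GRCh38) served first as a check of the labels, since the columns were assigned to lines from their names. It stood at 4808 ± 195 scaled TPM (SD, n = 3) in HBBko and 15782 ± 5710 in WT, a log2 fold change of -1.66 ± 0.17 (SE) with an adjusted p of 2.0e-06, so HBB transcripts remained present in HBBko cells at a 3.16-fold lower level. The fetal gamma-globin genes were higher in HBBko. HBG1 (chromosome 11, 5248079 to 5249859) was 33.8 ± 1.37 against 16.2 ± 4.85 (log2 fold change 1.05 ± 0.17, adjusted p = 0.00012), and HBG2 (start 5253190) was 329 ± 21.4 against 199.6 ± 62.6 (0.76 ± 0.20, adjusted p = 0.0057). Embryonic HBE1 was under 1 scaled TPM in both lines (0.803 ± 0.162 against 0.333 ± 0.12, log2 fold change 0.44, adjusted p = 0.0058, and 0.17 with a pseudocount of 5). HBD (0.01, adjusted p = 0.97), HBA1 (0.21, adjusted p = 0.37) and HBA2 (0.24, adjusted p = 0.30) were not called. HBA1 and HBA2 were called without replicate 3 of undifferentiated WT (0.52 and 0.55), under quantile normalization (0.32 and 0.39) and with library weights (0.39 and 0.40).

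Among the regulators named in advance, ATF4 (chromosome 22, 39519695 to 39522685), the transcription factor of the integrated stress response, was 292 ± 17.7 scaled TPM in undifferentiated HBBko cells and 578 ± 109 in WT cells (n = 3 each, log2 fold change -0.97 ± 0.09, adjusted p = 9.7e-07). MYB (chromosome 6, 135181315 to 135219173), a transcription factor of erythroid progenitors, differed far less, with 165 ± 4.003 against 189 ± 7.39 (-0.20 ± 0.06, adjusted p = 0.014). That call was lost with globins removed from the total (-0.17, adjusted p = 0.055), with rescaling to equal sums (-0.15, adjusted p = 0.13) and without HBBko replicate 2 (-0.18, adjusted p = 0.054). BCL11A (chromosome 2, 60450520 to 60555154), a repressor of gamma-globin, was 10.96 ± 0.177 against 13.3 ± 1.6 (-0.25 ± 0.08, adjusted p = 0.024). It was no longer called without WT replicate 3 (-0.16, adjusted p = 0.12), HBBko replicate 1 (-0.24, adjusted p = 0.063) or HBBko replicate 2 (-0.24, adjusted p = 0.06), under median-of-ratios scaling (-0.22, adjusted p = 0.055), with library weights (-0.20, adjusted p = 0.08), or in a fit of only these groups (adjusted p = 0.11). KLF1 (chromosome 19, 12884422 to 12887199), an activator of adult globin, was 303 ± 16.8 against 445 ± 80.3 (-0.54 ± 0.09, adjusted p = 0.00023). The heme-regulated eIF2alpha kinase EIF2AK1 (chromosome 7, 6022244 to 6059230) was also lower (-0.23, adjusted p = 0.0057).

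In undifferentiated cells 5197 genes were called, 2515 higher and 2682 lower in HBBko, and 198 of them differed at least 2-fold (71 higher, 127 lower). A fit of only these groups called 2882, fewer than the 4275 that such a fit called at 48 h. EYA4 (chromosome 6, 133240598 to 133532120), a phosphatase and transcriptional coactivator, had the largest increase, with 44.6 ± 2.39 scaled TPM against 1.26 ± 0.332 (log2 fold change 4.35, adjusted p = 3.2e-14), followed by the globin pseudogene HBBP1 (198 ± 5.51 against 39.4 ± 3.47, 2.30), CALB2 (1.97), RHOB (1.92) and CNN3 (1.78). EGR1 (1.49), KLHL23 (1.43), PRG2 (1.38), FOSL1 (1.35) and DDN (1.34) completed the named increases. CHAC1 (chromosome 15, 40952962 to 40956519), a glutathione-degrading enzyme and ATF4 target, had the largest decrease, with 2.87 ± 0.944 against 48.8 ± 25.9 (-3.60). PLS3 (chromosome X, 115561174 to 115650861), which encodes the actin-bundling plastin 3, was 0.652 ± 0.035 against 13.5 ± 1.75 (-3.13, adjusted p = 1.4e-12). RBMS1 (-2.69), SLFN13 (-2.59), ADM2 (-2.45), SESN2 (-2.34), INHBE (-2.29), CTH (-2.25) and PSAT1 (-2.24) followed.

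Of the lists, ATF4 and amino acid response targets moved most in undifferentiated cells: 39 of 42 tested members were lower in HBBko and none higher, 39 also when adjusted over the list alone (camera adjusted p = 2.7e-24, or adjusted p = 0.22 with an estimated correlation). Heat shock and cytosolic chaperones went the other way, with 23 of 24 higher and none lower, 23 adjusted over the list alone, among them HSPA1A (1.10), HSPA8 (0.80) and HSP90AA1 (0.75). Camera gave heat shock genes an adjusted p of 9.0e-12, or adjusted p = 0.17 with an estimated correlation. Cholesterol synthesis genes were higher, 14 of 21 against 1 lower (15 and 1 adjusted over the list alone), with a camera adjusted p of 7.4e-05 and an adjusted p of 0.61 with an estimated correlation, among them INSIG1 (1.05) and MSMO1 (0.76). Red cell membrane and skeleton genes were lower, 17 of 26 against 1 higher (17 and 1 adjusted over the list alone), including TSPO2 (-1.25), the anion exchanger SLC4A1 (-1.14) and AQP1 (-1.02). Camera gave red cell membrane genes an adjusted p of 9.7e-05, or adjusted p = 0.61 with an estimated correlation. In G2 and M phase 14 of 22 were lower and none higher (15 adjusted over the list alone), as TOP2A (-0.47) and CENPE (-0.42). Camera gave G2 and M genes an adjusted p of 0.0013, or adjusted p = 0.61 with an estimated correlation. In the proteasome 12 of 35 were higher and 1 lower, the same counts adjusted over the list alone, and 20 were higher without WT replicate 3. Camera gave the proteasome an adjusted p of 0.0018, or adjusted p = 0.61 with an estimated correlation. Of 32 globin regulators, 18 were lower and 1 higher (19 and 1 adjusted over the list alone), KLF3 (-0.64) and FOXO3 (-0.63) next to the genes above, and 8 were lower without HBBko replicate 2. Camera gave globin regulators an adjusted p of 0.0012, or adjusted p = 0.17 with an estimated correlation.

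ER chaperones and unfolded protein response genes split in undifferentiated cells, with 9 of 21 higher and 5 lower (10 and 5 adjusted over the list alone); HSPA5 (1.05) and MANF (1.03) rose and HERPUD1 (-1.28) fell. Their camera adjusted p was 0.042, and the adjusted p was 0.17 with an estimated correlation; the call was lost with rescaling to equal sums (0.067), without WT replicate 3 (0.062) and without HBBko replicate 1 (0.057). Heme synthesis and transport had 12 of 21 lower and 3 higher, also adjusted over the list alone, led by ALAD (-0.86), and was not called. Camera gave heme synthesis an adjusted p of 0.070, or adjusted p = 0.69 with an estimated correlation. It was called with globins removed (0.029), with rescaling to equal sums (0.021), with a block on the replicate number (0.042), and without WT replicate 1 (0.034) or 2 (0.020). The globin list had 4 of 10 higher and 1 lower, also adjusted over the list alone, but 7 higher and a camera adjusted p of 0.0083 without WT replicate 3. Camera gave globins an adjusted p of 0.22, or adjusted p = 0.81 with an estimated correlation. Of 7 mast cell, basophil and eosinophil markers 3 were higher and 1 lower, also adjusted over the list alone, as PRG2 (1.38) and GATA2 (0.95); the camera adjusted p was 0.081 (adjusted p = 0.61 with an estimated correlation), and 0.039 without WT replicate 1 or without HBBko replicate 2.

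The 48 h comparison asks what beta-globin loss changes early in differentiation. HBB was 23097 ± 1092 scaled TPM in HBBko and 111681 ± 18343 in WT (SD, n = 3; log2 fold change -2.26 ± 0.17, adjusted p = 1.4e-07). HBG1 was 528 ± 32.4 against 161 ± 27.6 (1.72, adjusted p = 3.2e-06), HBG2 6155 ± 243 against 2174 ± 523 (1.53, adjusted p = 6.0e-05) and HBE1 4.11 ± 0.0968 against 1.33 ± 0.137 (1.14, adjusted p = 3.8e-06). HBD fell from 74.9 in WT to 28.0 scaled TPM in HBBko (-1.37, adjusted p = 1.4e-06). HBA1 and HBA2 were both at -0.13 (adjusted p = 0.68 for each) and turned to 0.60 and 0.42 under quantile normalization. ATF4 was 267 ± 0.962 against 394 ± 24.1 (-0.56, adjusted p = 0.00061), BCL11A 8.59 ± 0.371 against 13.03 ± 0.377 (-0.55, adjusted p = 0.00029) and KLF1 479 ± 17.3 against 662 ± 46.4 (-0.46, adjusted p = 0.0024). MYB was not called, at 71.4 ± 1.61 against 77.4 ± 7.16 (-0.11, adjusted p = 0.22), but was called with library weights (-0.16, adjusted p = 0.0020) and without WT replicate 3 (-0.19, adjusted p = 0.044). EIF2AK1 was not called (-0.13, adjusted p = 0.13) except without WT replicate 1 (-0.20, adjusted p = 0.031).

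At 48 h 2249 genes were called, 1143 higher and 1106 lower in HBBko, 110 of them at least 2-fold (24 higher, 86 lower). The count fell to 1179 without WT replicate 3, 1432 without HBBko replicate 1, 1445 without HBBko replicate 2 and 1409 without HBBko replicate 3, and rose to 5189 with library weights, 4275 in a fit of only these groups and 4191 with rescaling to equal sums. The median over all tested genes was 0.02, and 50.8% of called genes were higher; with rescaling to equal sums these were 0.14 and 84.2%. EYA4 (3.14) again led the increases, followed by HBBP1 (2.43), SERPINB1 (1.97), CNN3 (1.95) and CYTL1 (1.75), and embryonic zeta-globin HBZ rose from 71.1 ± 3.91 to 194 ± 7.12 scaled TPM (1.43). PAPSS1 (1.38) and SSUH2 (1.33) were the last. RBMS1 (-3.07), CA3 (-2.59), PLS3 (-2.49), CHAC1 (-2.28), PITX1 (-2.28), DDIT4 (-2.12), TNXB (-2.05), COX6B2 (-1.87) and GPT2 (-1.82) led the decreases beside HBB.

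ATF4 targets, heat shock genes and cholesterol synthesis genes kept their directions at 48 h. Of 42 ATF4 and amino acid response targets, 35 were lower and none higher in HBBko (37 lower adjusted over the list alone), among them PSAT1 (-1.76). Camera gave ATF4 targets an adjusted p of 1.1e-28, or adjusted p = 0.10 with an estimated correlation. Of 24 heat shock and cytosolic chaperones, 18 were higher and none lower (19 adjusted over the list alone), as CHORDC1 (0.51), HSPH1 (0.51) and HSP90AA1 (0.47). Camera gave heat shock genes an adjusted p of 2.3e-09, or adjusted p = 0.10 with an estimated correlation. Of 21 cholesterol synthesis genes, 15 were higher and none lower (16 and 1 adjusted over the list alone), as DHCR7 (0.64). Camera gave cholesterol synthesis an adjusted p of 1.1e-06, or adjusted p = 0.22 with an estimated correlation. In glycolysis and the hypoxia response 10 of 24 were higher and 4 lower (12 and 4 adjusted over the list alone), ENO1 (0.68), ALDOC (0.57) and GPI (0.56) among them. Camera gave glycolysis an adjusted p of 0.0037, or adjusted p = 0.19 with an estimated correlation. Late erythroid maturation had 13 of 28 lower and none higher (14 adjusted over the list alone), including TSPO2 (-1.18), TMCC2 (-0.64) and ARG1 (-0.63). Camera gave late erythroid genes an adjusted p of 1.1e-06, or adjusted p = 0.24 with an estimated correlation. Red cell membrane and skeleton genes had 10 of 26 lower and none higher, also adjusted over the list alone, with 6 lower and 1 higher without WT replicate 3. Camera gave red cell membrane genes an adjusted p of 2.3e-06, or adjusted p = 0.24 with an estimated correlation. Core histones had 6 of 15 lower and none higher, also adjusted over the list alone, as HIST1H4C (-1.09) and HIST1H1D (-1.05), and 3 lower without WT replicate 3 or HBBko replicate 2. Camera gave histones an adjusted p of 0.0012, or adjusted p = 0.24 with an estimated correlation. Of 14 interferon response genes 5 were lower and 1 higher, also adjusted over the list alone, led by RSAD2 (-0.67) and IRF1 (-0.66). Camera gave interferon genes an adjusted p of 0.012, or adjusted p = 0.10 with an estimated correlation.

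Another 9 lists were called at 48 h, most with few called members. Of 35 proteasome genes 16 were higher and none lower (19 and 1 adjusted over the list alone), PSMA3 (0.43) first, with 10 higher without WT replicate 1 or 3 or HBBko replicate 1 and 9 without HBBko replicate 3. Of 32 globin regulators 10 were lower and 1 higher, also adjusted over the list alone, as SOX6 (-0.60) and KLF3 (-0.48). Of 24 S phase and replication genes 7 were higher and 1 lower (8 and 2 adjusted over the list alone), CDC45 (0.28) against E2F2 (-0.58), with 4 higher without HBBko replicate 3. Of 20 cell cycle arrest and p53 targets 6 were lower and 1 higher (8 and 1 adjusted over the list alone), BBC3 (-0.70) against CDKN1A (0.86). Early progenitor genes had 4 of 15 lower and 2 higher (5 and 2 adjusted over the list alone), led by CDK6 (-1.77), and were not called without WT replicate 2 (adjusted p = 0.064). Iron uptake and handling had 7 of 22 lower and 1 higher, also adjusted over the list alone, as TFRC (-0.32), with 4 lower without WT replicate 2 and 3 without WT replicate 3 or HBBko replicate 1, 2 or 3. G2 and M phase had 3 of 22 lower and none higher, also adjusted over the list alone, as MKI67 (-0.29; adjusted p = 0.09 with rescaling to equal sums). Autophagy and mitophagy had 4 of 28 lower and none higher, also adjusted over the list alone, as OPTN (-0.69), with 2 lower without WT replicate 3 or HBBko replicate 2. The respiratory chain had 4 of 28 higher and none lower (2 adjusted over the list alone), as ATP5F1B (0.16), with none higher without WT replicate 3, 1 without WT replicate 1 or HBBko replicate 3 and 2 without HBBko replicate 1 or 2. In the order given here the camera adjusted p was 1.1e-06, 0.0013, 0.012, 0.0071, 0.023, 0.0065, 0.0012, 0.0041 and 0.00032. With an estimated correlation the adjusted p was 0.20, 0.10, 0.10, 0.10, 0.24, 0.19, 0.31, 0.24 and 0.31. With rescaling to equal sums the call was lost for iron handling (3 higher, 1 lower, adjusted p = 0.21) and for G2 and M phase (3 higher, 1 lower, adjusted p = 0.10), and the counts turned to 6 higher and 2 lower for autophagy and to 3 each for early progenitor genes.

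The 5 d comparison asks what the loss of HBB changes late in differentiation, when globin output is high. HBB was 70806 ± 1823 scaled TPM in HBBko and 439258 ± 16960 in WT (SD, n = 3; log2 fold change -2.63 ± 0.17, adjusted p = 3.3e-09), a 6.20-fold lower level. HBG1 was 3449 ± 238 against 327 ± 79.4 (3.42, adjusted p = 1.9e-10) and HBG2 46038 ± 5297 against 4335 ± 1149 (3.43, adjusted p = 9.4e-10), 10.7-fold and 10.8-fold higher. HBE1 was 14.98 ± 2.98 against 1.94 ± 0.192 (2.43, adjusted p = 1.1e-10) and HBZ 173 ± 40.0 against 17.8 ± 1.67 (3.19). HBA1 (0.08, adjusted p = 0.74), HBA2 (0.13, adjusted p = 0.58) and HBD (-0.20, adjusted p = 0.21) were not called; HBA1 and HBA2 were called under quantile normalization (0.60 and 0.42) and with rescaling to equal sums (0.42 and 0.47), and HBD in a fit of only these groups (adjusted p = 0.0015). BCL11A was 12.4 ± 0.476 against 21.8 ± 2.84 (-0.77, adjusted p = 1.2e-06). ATF4 did not differ detectably (731 ± 54.5 against 732 ± 27.2, adjusted p = 0.98) and was higher with rescaling to equal sums (0.33, adjusted p = 0.00080). MYB was 8.78 ± 0.338 against 10.5 ± 0.591 (-0.24, adjusted p = 0.0034), KLF1 1048 ± 41.7 against 1377 ± 51.6 (-0.39, adjusted p = 0.0020) and EIF2AK1 was lower (-0.32, adjusted p = 0.00025). With rescaling to equal sums these 3 calls were lost, at 0.07 (adjusted p = 0.48) for MYB, -0.06 (adjusted p = 0.53) for KLF1 and 0.01 for EIF2AK1.

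At 5 d 6157 genes were called, 3183 higher and 2974 lower in HBBko, 417 of them at least 2-fold (119 higher, 298 lower). The median over all tested genes was 0.02 and 51.7% of called genes were higher; with rescaling to equal sums these were 0.27 and 86.0%. Beside the globins and HBBP1 (3.10), the largest increases were in SSUH2 (2.65), the linker histone HIST1H1C (381 ± 89.1 against 66.8 ± 5.03, 2.47) and RUNX1T1 (2.27). Beside HBB, PLS3 (-3.55), the argininosuccinate synthase ASS1 (-3.02), heme oxygenase HMOX1 (13.1 ± 2.43 in HBBko and 98.1 ± 17.2 in WT, -2.81), TMSB4X (-2.47), RBMS1 (-2.46), TRIB3 (-2.44) and TXNIP (-2.43) decreased most.

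ATF4 and amino acid response targets were lower at 5 d in 32 of 42 and higher in none (32 and 1 adjusted over the list alone), with STC2 (-2.21), SESN2 (-1.79) and PHGDH (-1.66) after TRIB3 (-2.44); with rescaling to equal sums 25 were lower and 7 higher. Camera gave ATF4 targets an adjusted p of 2.1e-09, or adjusted p = 0.34 with an estimated correlation. Heat shock and cytosolic chaperones were higher in 17 of 24 and lower in 1, also adjusted over the list alone, as BAG3 (1.35). Camera gave heat shock genes an adjusted p of 3.8e-05, or adjusted p = 0.28 with an estimated correlation. Cholesterol synthesis genes were higher in 17 of 21 and lower in 2, also adjusted over the list alone, with SQLE (1.43) and DHCR7 (1.34). Camera gave cholesterol synthesis an adjusted p of 4.2e-07, or adjusted p = 0.28 with an estimated correlation. Proteasome genes were higher in 28 of 35 and lower in none (29 adjusted over the list alone), as PSMA3 (0.64). Camera gave the proteasome an adjusted p of 2.8e-07, or adjusted p = 0.27 with an estimated correlation. Mitochondrial respiratory chain genes were higher in 19 of 28 and lower in none, also adjusted over the list alone, as NDUFA9 (0.49). Camera gave the respiratory chain an adjusted p of 1.3e-05, or adjusted p = 0.30 with an estimated correlation. Ribosomal proteins were higher in 22 of 44 and lower in 1, also adjusted over the list alone, as RPL23 (0.79), with RPS7 lower (-1.01). Camera gave ribosomal proteins an adjusted p of 9.2e-05, or adjusted p = 0.57 with an estimated correlation. G2 and M phase genes, lower in the undifferentiated comparison, were higher in 13 of 22 and lower in 2, also adjusted over the list alone, as CCNB1 (0.45). Camera gave G2 and M genes an adjusted p of 0.014, or adjusted p = 0.57 with an estimated correlation.

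The lists that follow were lower at 5 d, unlike the heat shock chaperones and the proteasome above, and several of them turn with rescaling to equal sums. The oxidative stress response was lower in 15 of 24 and higher in 2, also adjusted over the list alone, with OSGIN1 (-1.58) and GPX4 (-1.03) after HMOX1 (-2.81), and in 11 lower and 7 higher when rescaled. Camera gave oxidative stress genes an adjusted p of 3.2e-05, or adjusted p = 0.15 with an estimated correlation. ER chaperones and the unfolded protein response were lower in 12 of 21 and higher in 4 (12 and 5 adjusted over the list alone), with SEL1L (-1.51), HSPA5 (-1.13) and CALR (-0.97), but in 8 lower and 9 higher when rescaled. Camera gave ER chaperones an adjusted p of 0.014, or adjusted p = 0.15 with an estimated correlation. Iron uptake and handling was lower in 14 of 22 and higher in 2 (14 and 3 adjusted over the list alone), including the ferritin genes FTH1 (-0.92) and FTL (-0.72), but in 4 lower and 9 higher when rescaled. Camera gave iron handling an adjusted p of 0.0083, or adjusted p = 0.27 with an estimated correlation. Cell cycle arrest and p53 targets were lower in 11 of 20 and higher in 1, also adjusted over the list alone, as CDKN1A (-1.88) and TNFRSF10B (-1.28). Camera gave p53 targets an adjusted p of 0.0067, or adjusted p = 0.15 with an estimated correlation. Autophagy and mitophagy was lower in 15 of 28 and higher in 5 (16 and 5 adjusted over the list alone), as GABARAPL1 (-0.97), but in 5 lower and 12 higher when rescaled. Camera gave autophagy an adjusted p of 0.017, or adjusted p = 0.34 with an estimated correlation. Late erythroid maturation was lower in 17 of 28 and higher in 3, also adjusted over the list alone, with TMCC2 lower (-1.25) and TRIM10 higher (1.32), but in 7 lower and 11 higher when rescaled. Camera gave late erythroid genes an adjusted p of 0.00055, or adjusted p = 0.45 with an estimated correlation. Early progenitor genes were lower in 9 of 15 and higher in 1, also adjusted over the list alone, as CDK6 (-1.84) and CD44 (-0.80). Camera gave early progenitor genes an adjusted p of 0.014, or adjusted p = 0.29 with an estimated correlation.

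The other lists were not called at 5 d. The fetal and neonatal programme had 2 of 7 higher, HBG1 and HBG2, and 3 lower (2 and 4 adjusted over the list alone); its median was -0.25 and its mean 0.69, camera gave lower and fry higher, and the counts turned to 2 higher and 1 lower with rescaling to equal sums. Camera gave the fetal programme an adjusted p of 0.88, or adjusted p = 0.90 with an estimated correlation. The eIF2alpha kinase and phosphatase list had 5 of 17 higher and 2 lower, also adjusted over the list alone, with DELE1 at 0.81. Camera gave the eIF2alpha list an adjusted p of 0.18, or adjusted p = 0.30 with an estimated correlation. S phase and replication had 5 of 24 higher and 4 lower, also adjusted over the list alone, and 4 each under median-of-ratios scaling, as E2F1 (-0.75). Camera gave S phase genes an adjusted p of 0.86, or adjusted p = 0.90 with an estimated correlation. Nuclear condensation and chromatin had 5 of 22 higher and 7 lower (5 and 9 adjusted over the list alone), RIOK3 at -1.05, and turned to 6 higher and 5 lower under quantile normalization and 11 and 3 with rescaling to equal sums. Camera gave nuclear condensation an adjusted p of 0.46, or adjusted p = 0.57 with an estimated correlation. Of 4 myeloid markers none was higher and 2 were lower, also adjusted over the list alone, AZU1 (-0.77) and CEBPA (-0.42). Camera gave myeloid markers an adjusted p of 0.12, or adjusted p = 0.29 with an estimated correlation. Of 4 megakaryocyte markers 2 were higher and none lower, also adjusted over the list alone, GP1BB (0.75) and TUBB1 (0.37); TUBB1 was not called without WT replicate 1 (adjusted p = 0.085) or 2 (0.057) or HBBko replicate 2 (0.099) or 3 (0.085). Camera gave megakaryocyte markers an adjusted p of 0.48, or adjusted p = 0.58 with an estimated correlation. Of 3 stromal and endothelial markers 1 was lower, VIM (-0.64), also adjusted over the list alone, and 1 was higher with rescaling to equal sums. Camera gave stromal markers an adjusted p of 0.48, or adjusted p = 0.57 with an estimated correlation. No list call between the lines at any of the 3 stages held with an estimated correlation.

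**Figure D1:**
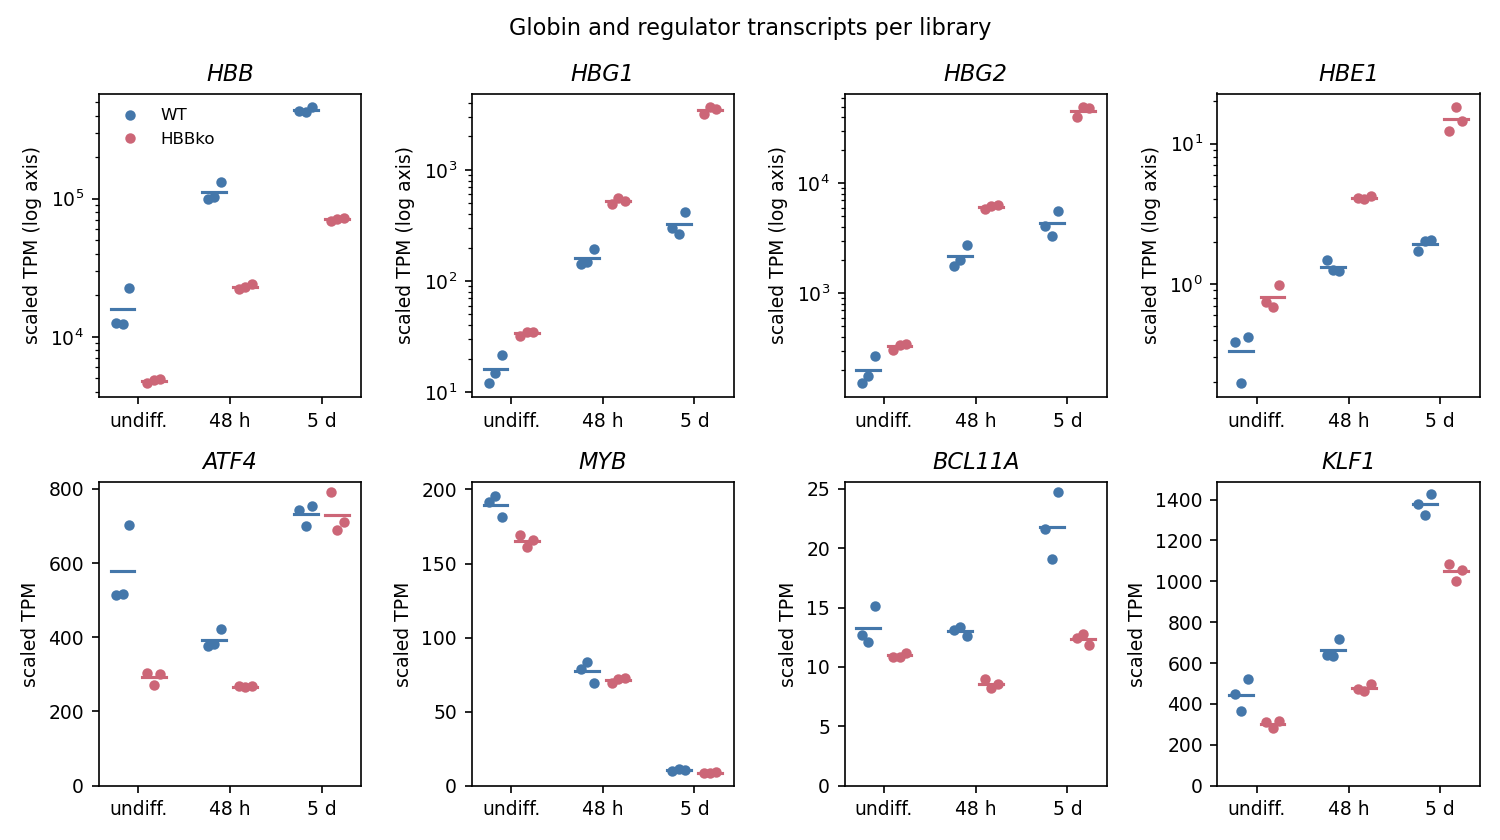
Scaled TPM per library (vertical axes, logarithmic for HBB, HBG1, HBG2 and HBE1, linear from 0 for ATF4, MYB, BCL11A and KLF1) by stage (horizontal axis), each point 1 library, lines the group means, WT in blue and HBBko in red. HBG2 at 5 d was 46038 in HBBko against 4335 in WT, and ATF4 was 292 against 578 in undifferentiated cells and 731 against 732 at 5 d.

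**Figure D2:**
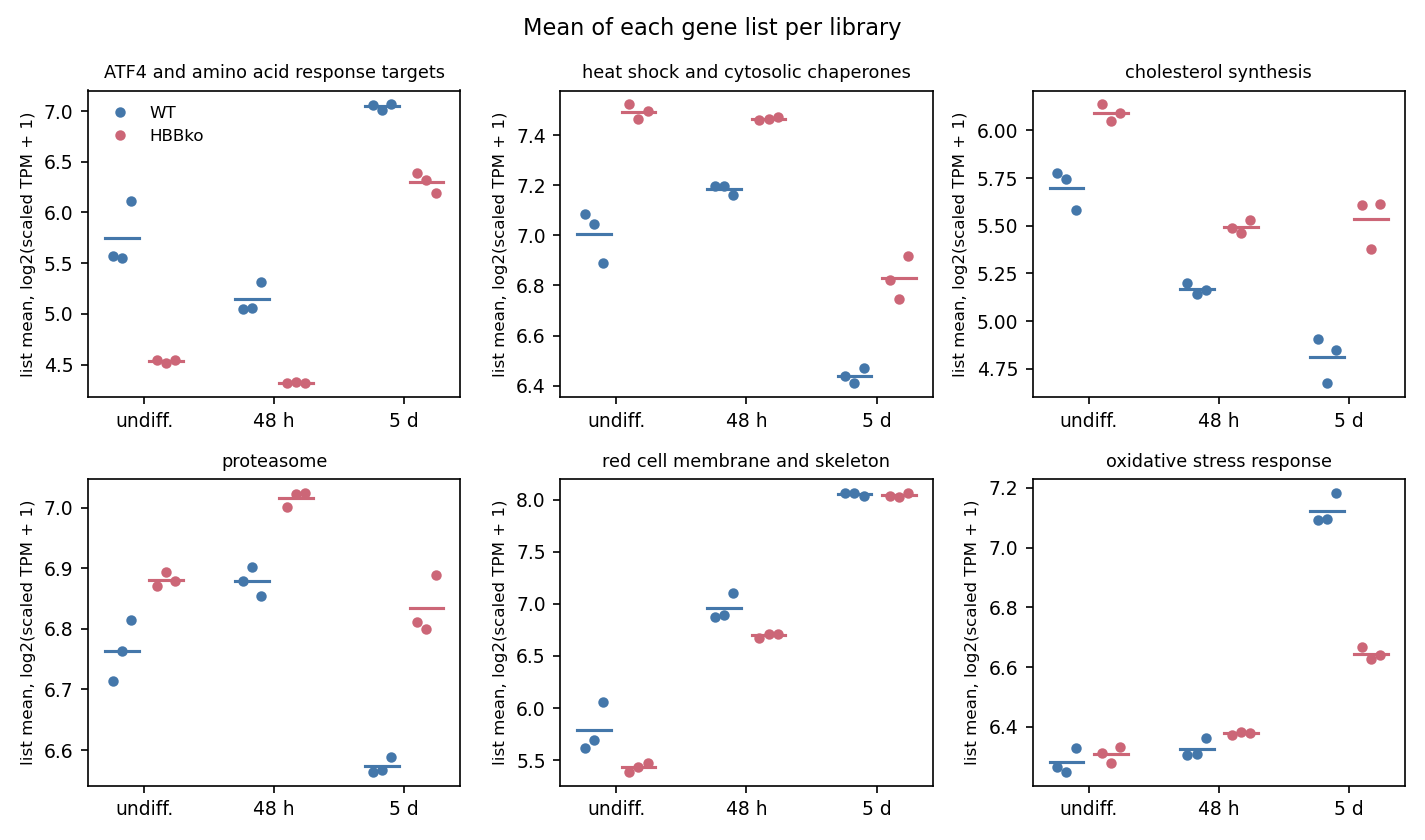
Mean log2(scaled TPM + 1) of a gene list (vertical axis) by stage (horizontal axis) for 6 lists, each point 1 library, WT in blue and HBBko in red. HBBko libraries lay below WT for ATF4 targets and above WT for heat shock and cholesterol synthesis genes, with list medians of -1.11, 0.53 and 0.40 in undifferentiated cells.

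**Figure D3:**
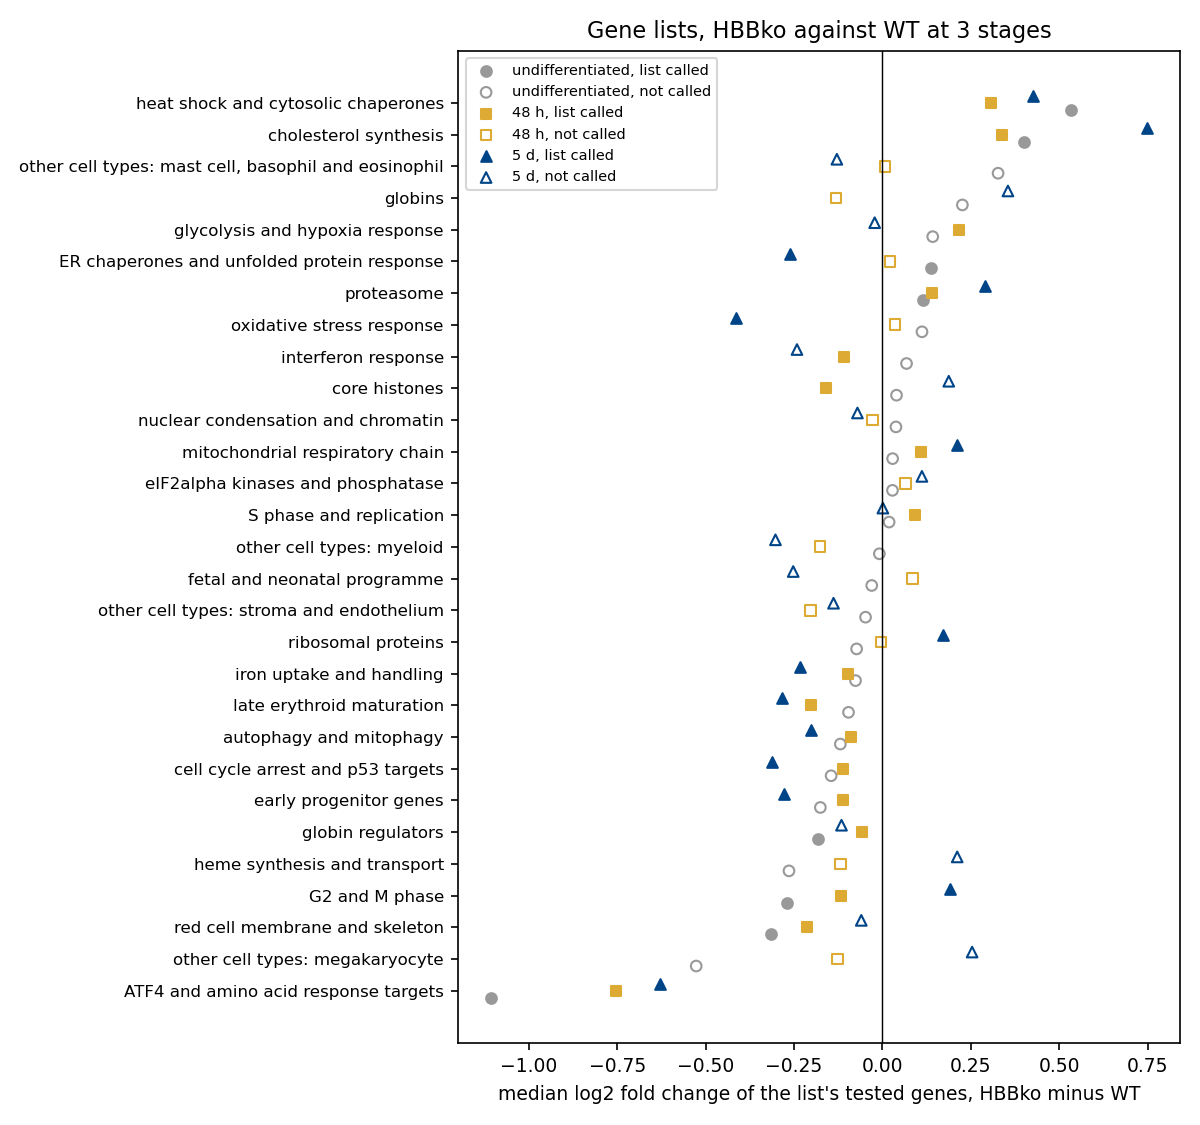
Median log2 fold change of HBBko against WT (horizontal axis) of the tested genes of each list (vertical axis) at the 3 stages, filled points for lists called by camera at its preset correlation and open points for the others. The list of ATF4 and amino acid response targets stood lowest at the 3 stages, at -1.11, -0.75 and -0.63.

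Gamma-globin took 6.999% ± 0.176 (SD, n = 3) of beta-like globin signal in undifferentiated HBBko cells against 1.36% ± 0.135 in WT, 22.4% ± 0.426 against 2.03% ± 0.147 at 48 h, and 40.9% ± 2.30 against 1.04% ± 0.231 at 5 d. The lines did not overlap at any stage, and each exact permutation p was 0.1, the smallest that 3 libraries against 3 allow (0.111 adjusted over the 21 quantities of this kind). The ratio of alpha-like to beta-like signal was 1.58 against 0.456 in undifferentiated cells, 2.78 against 0.801 at 48 h and 2.81 against 0.704 at 5 d (exact permutation p = 0.1 for each). Both quantities have HBB in the denominator and so also reflect its loss. The beta-like sum in HBBko was 0.324, 0.261 and 0.272 times that of WT at the 3 stages in order. The gamma-globin sum was 1.68, 2.86 and 10.6 times that of WT, and the alpha-like sum 1.11, 0.907 and 1.08 times. The beta-like, gamma-globin and alpha-like sums keep the scaling of the deposited values. Library totals at 5 d were lower in HBBko than in WT, so with equal totals these ratios would be higher at that stage. Globins took 1.69%, 13.2% and 39.3% of all signal in HBBko at the 3 stages and 2.83%, 21.7% and 51.3% in WT. Zeta-globin took 0.0511% of alpha-like signal in HBBko at 5 d and 0.00569% in WT.

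Across the 3 stages, 420 genes were higher in HBBko at each stage and 498 lower, against 63.5 and 61.2 if the calls were independent between stages. The calls are not independent, since the comparisons share the same 2 lines and 1 spread per gene, so this excess is no test of a shared effect. The total of 918 genes called in 1 direction fell to 592 without WT replicate 3 at 48 h and rose to 1487 with rescaling to equal sums. In 38 genes the difference was at least 2-fold in the same direction at every stage, among them EYA4, HBG1, HBZ, SERPINB1 and CNN3 (higher) and HBB, PLS3, RBMS1, CHAC1, SESN2 and TRIB3 (lower). Another 958 genes were higher at 1 stage and lower at another. Log2 fold changes correlated across genes, which are not independent replicates, at 0.59 between undifferentiated and 48 h, 0.53 between 48 h and 5 d and 0.25 between undifferentiated and 5 d.

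Interactions ask whether the difference between the lines changed with stage. From undifferentiated to 5 d, 5405 genes were called, 2825 toward higher and 2580 toward lower values in HBBko (52.3% higher, 82.4% with rescaling to equal sums, which moved the median over all genes from 0.02 to 0.25). The HBBko excess of HBG1 grew by 2.37 ± 0.24 (SE, adjusted p = 1.5e-06) and that of HBG2 by 2.68 ± 0.28 (adjusted p = 2.2e-06) on the log2 scale, and the deficit of HBB changed by -0.97 ± 0.24 (adjusted p = 0.0038; adjusted p = 0.07 with no filter, and 1.73 under quantile normalization). The deficit of ATF4 closed (0.96 ± 0.13, adjusted p = 2.7e-05), and the deficit of BCL11A, which rose less in HBBko than in WT, widened (-0.52 ± 0.12, adjusted p = 0.0022; -0.23 with an adjusted p of 0.096 with rescaling to equal sums). Beside HBG1 and HBG2, TSPAN32 (2.52), CHAC1 (2.40) and NEIL1 (2.32) moved up most, and HMOX1 (-3.22), EGR1 (-2.58), EYA4 (-2.53) and TMSB4X (-2.42) moved down most.

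From 48 h to 5 d, 2958 genes were called for interaction (1381 toward higher, 1577 toward lower; 46.7% higher, 80.8% with rescaling to equal sums, where the median over all genes was 0.15), and 4682 with library weights. HIST1H1C (2.56), FTCD (1.93), HBG2 (1.91; 0.44 with an adjusted p of 0.24 under quantile normalization) and HBZ (1.76) moved up, and HMOX1 (-4.03), CDKN1A (-2.74), MT2A (-2.27) and MT1G (-2.27) moved down. From undifferentiated to 48 h, 1582 genes were called (921 toward higher, 661 toward lower; 58.2% higher, 84.6% with rescaling to equal sums). That count moved when single libraries were left out. It was 2481 without undifferentiated WT replicate 1, 967 without WT 48 h replicate 1 and 830 without undifferentiated HBBko replicate 1. It was 888, 926 and 998 without HBBko 48 h replicates 1, 2 and 3. A fit with a library left out has fewer libraries, so a lower count does not by itself show that 1 library carried the calls. The gains of HBG1 (0.67, adjusted p = 0.076) and HBG2 (0.77, adjusted p = 0.082) over this interval were not called, but were called without undifferentiated WT replicate 1 (0.85 and 0.94) and without WT 48 h replicate 3 (0.80 and 0.95), with rescaling to equal sums (0.76 and 0.87), and with a block on the replicate number (adjusted p = 0.025 and 0.021). INHBE (2.27) moved up most, and RHOB (-1.98) and CALB2 (-1.92) moved down most.

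ER chaperones and the unfolded protein response shifted down in HBBko relative to WT from undifferentiated to 5 d, 13 of 21 members down and 3 up (14 and 3 adjusted over the list alone), with HSPA5 (-2.19), MANF (-1.58) and SEL1L (-1.44). The camera adjusted p was 0.00018, and the adjusted p was 0.018 with an estimated correlation. From 48 h to 5 d 9 were down and 1 up (10 and 1 adjusted over the list alone; camera adjusted p = 0.00091, adjusted p = 0.025 with an estimated correlation). The oxidative stress response shifted down from 48 h to 5 d in 16 of 24 members and up in 3, also adjusted over the list alone, with HMOX1 (-4.03) and OSGIN1 (-1.40) down and SLC7A11 (0.86) up. Camera gave oxidative stress genes an adjusted p of 3.8e-07, or adjusted p = 0.025 with an estimated correlation. The ATF4 target deficit lessened from undifferentiated to 5 d, with 23 of 42 up and 5 down, also adjusted over the list alone, though the list stayed lower in HBBko at 5 d. Camera gave ATF4 targets an adjusted p of 0.00091, or adjusted p = 0.60 with an estimated correlation. In all of these the direction by camera was the same under median-of-ratios scaling, with globins removed and with rescaling to equal sums.

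Differentiation within each line gives the background for these differences. In WT cells 7790 genes were called at 48 h (2816 higher, 4974 lower, 1475 at least 2-fold) and 10306 at 5 d (3604 higher, 6702 lower, 4813 at least 2-fold). In HBBko cells 7822 were called at 48 h (3009 higher, 4813 lower, 1474 at least 2-fold) and 10294 at 5 d (3764 higher, 6530 lower, 4773 at least 2-fold). The median over all genes was -0.10 and -0.36 in WT and -0.09 and -0.33 in HBBko at the 2 stages, and changes within a line are to be read against that shift. At 5 d in WT it was -0.09 under median-of-ratios scaling, -0.25 with globins removed, 0.02 under quantile normalization and -1.06 with rescaling to equal sums; in HBBko these were -0.10, -0.21, 0.05 and -0.80. At 48 h it was 0.02 under median-of-ratios scaling, 0.07 under quantile normalization and -0.28 with rescaling to equal sums in WT, and 0.06 under quantile normalization and -0.18 with rescaling to equal sums in HBBko. The share of called genes that were higher moved with it, from 36.1% to 51.0%, 47.2%, 55.7% and 19.2% in WT at 48 h under the 4 scalings in the order median-of-ratios, globins removed, quantile and equal sums. At 5 d in WT it moved from 35.0% to 46.1% (median-of-ratios), 50.5% (quantile) and 14.3% (equal sums), in HBBko at 48 h from 38.5% to 49.3% (median-of-ratios), 55.2% (quantile) and 29.3% (equal sums), and in HBBko at 5 d from 36.6% to 51.2% (quantile) and 20.8% (equal sums).

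The largest increases in WT at 5 d were in the stress cytokine GDF15 (962 ± 47.7 against 12.9 ± 5.15 scaled TPM, n = 3, log2 fold change 6.18), HBD (6.06), the water channel AQP1 (5.81), RUNDC3A (5.81) and ARG1 (5.77), and the largest decreases in vimentin VIM (-7.33), the mast cell tryptase TPSAB1 (-6.99), HPGD (-6.70), RHEX (-6.51) and TPSB2 (-6.46). HBBko cells at 5 d shared AQP1 (7.06) and added HBG2 (7.12), HBG1 (6.63), TRIM10 (6.62) and SLC4A1 (6.46), with VIM (-7.91), TPSAB1 (-7.61), TPSB2 (-7.23), HPGD (-7.06) and RHEX (-6.57) lowest. At 48 h AQP1 (4.31), HBM (3.95), FCGRT (3.95), HBA2 (3.83) and MT1G (3.66) rose most in WT, and MT1G (5.38), AQP1 (4.55), FCGRT (4.23), HBG2 (4.22) and MT1H (4.15) in HBBko. TPSAB1 (-6.15), TPSB2 (-5.74), PKM (-5.56), RHEX (-5.55) and SIGLEC6 (-5.52) fell most in WT at 48 h, and TPSAB1 (-6.17), PKM (-5.97), TPSB2 (-5.86), PALM2-AKAP2 (-5.57) and TMSB4X (-5.43) in HBBko. MYB changed by -1.28 and -4.05 at 48 h and 5 d in WT and by -1.20 and -4.09 in HBBko.

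Erythroid lists rose in both lines. At 5 d red cell membrane and skeleton genes were higher in 23 of 26 and lower in 2 in WT, and higher in 25 and lower in 1 in HBBko, in each line also adjusted over the list alone. The camera adjusted p was 9.5e-11 in WT and 3.7e-12 in HBBko, or adjusted p = 0.17 and 0.13 with an estimated correlation. Late erythroid maturation was higher in 28 of 28 in WT, and in 27 with 1 lower in HBBko, in each line also adjusted over the list alone. Its camera adjusted p was 3.9e-15 in WT and 2.3e-13 in HBBko, or adjusted p = 0.11 and 0.13 with an estimated correlation. In WT, ATF4 and amino acid response targets were lower in 30 of 42 and higher in 3 at 48 h, then higher in 33 and lower in 3 at 5 d, at each stage also adjusted over the list alone. Their camera adjusted p was 0.0022 at 48 h and 3.6e-08 at 5 d, or adjusted p = 0.53 and 0.33 with an estimated correlation. In HBBko these targets were higher in 36 and lower in 4 at 5 d, also adjusted over the list alone, as CHAC1 (5.12), with a camera adjusted p of 2.7e-10, or adjusted p = 0.27 with an estimated correlation. Mast cell, basophil and eosinophil markers were lower in 7 of 7 at 48 h in both lines, also adjusted over the list alone. Their camera adjusted p was 2.2e-05 in WT and 7.8e-06 in HBBko, or adjusted p = 0.14 and 0.052 with an estimated correlation. The directions given here were the same under median-of-ratios scaling, with globins removed, under quantile normalization and with rescaling to equal sums, the last with 21 ATF4 targets higher and 14 lower in WT at 5 d.

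The authors' tables list 3648, 4522 and 6401 genes with a q under 0.05 at the 3 stages in order. Of the 11450, 11507 and 11335 genes in both sources, 3254, 2164 and 5383 were called by both, all in the same direction, against 1469, 806 and 3084 if the calls were independent. Log2 fold changes of the 2 sources correlated at 0.927, 0.877 and 0.919 across genes, which are not independent replicates and come from the same libraries. The authors' table gives MYB a q of 0.078, 0.21 and 0.0012, BCL11A a q of 0.051, 1.6e-18 and 2.9e-11, and ATF4 a q of 3.1e-07, 1.1e-19 and 0.94. For HBB it gives -1.67, -2.28 and -2.64 on the log2 scale, without a p or q in undifferentiated cells and at 48 h.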

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

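The tests of ATF4 targets, the whole-chromosome test, the maturation shares with 1 library left out and the use of early progenitor genes to weigh maturation were chosen only after the results were seen; the other tests of this part were written down before.

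The same fit was run on other splits of the libraries into groups of 3. For undifferentiated HBBko against WT, 1 of 10 splits, the real one, called as many as 5197 genes (highest other 5), at 48 h 1 of 10 (2249, highest other 1) and at 5 d 1 of 10 (6157, highest other 3). For WT at 48 h and 5 d and HBBko at 48 h and 5 d against undifferentiated cells it was likewise 1 of 10 each (7790, 10306, 7822 and 10294 genes, highest other 0). With 10 splits there are too few for a share under 0.05. For interactions, 100 splits were drawn. From undifferentiated to 5 d 1 of 100 reached the real 5405 (highest other 3430), from undifferentiated to 48 h 6 of 100 reached the real 1582 (highest other 5403), and from 48 h to 5 d 5 of 100 reached the real 2958 (highest other 6047). Every other split that called as many kept the lines whole at 1 or both stages and so still held the difference between them, which points to that structure of the samples. Splits that kept them whole at neither stage called at most 2, 2 and 1 genes, but they mix the lines within each group. Neither kind stands for an absence of interaction, so whether chance is excluded cannot be told from these splits for any of the 3 interactions.

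ATF4 targets were lower in HBBko at all 3 stages although ATF4 transcripts, the only measure of ATF4 here, were not lower at 5 d. Library scaling does not account for this, since the highest list median over 3 stages and 4 other scalings was -0.34, and neither does WT replicate 3 alone, with a highest median of -0.62 once it is left out. Culture state at harvest stays open. The largest range of the list mean within a group was 46.5% of the gap between the lines. It came from undifferentiated WT cells (gap 1.21, WT range 0.56 and HBBko range 0.04 on the log2 scale). That range cannot decide the question, because a state shared by all libraries of a group leaves no range within the group. Whether the cause is HBB loss, the state of the cultures or a difference between clones cannot be told from these libraries, and the last was not tested.

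In 38 genes the lines differed at least 2-fold in the same direction at every stage. A gained or lost chromosome would shift its median, but the largest chromosome median in size was 0.0833 over the 3 stages, and 1 deleted or duplicated segment would hold most of these genes, but the chromosome with most of them held 13.2% (5 of 38, spread over 20 chromosomes). Neither accounts for the set, of which 7 are in the ATF4 target list. Divergence between the 2 lines unrelated to HBB stays open and was not tested.

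Red cell membrane genes were lower in HBBko in undifferentiated cells and at 48 h. If WT libraries were further along differentiation, called genes would lie against the later WT change, and 61.8% of them did in undifferentiated cells (WT change from 48 h to 5 d) and 80.8% at 48 h (WT change from undifferentiated to 5 d). With 1 library left out these were 60.5% to 63.7% and 73.5% (without WT 48 h replicate 3) to 82.5%. Early progenitor genes, of which 12 of 15 were lower in WT at 48 h than before, were not higher in HBBko as a plain lag would have them: 7 were lower and 3 higher in undifferentiated cells (camera adjusted p = 0.32, not called), and 4 lower and 2 higher at 48 h (0.023, but 0.24 with an estimated correlation and 0.064 without WT replicate 2, and 3 each with rescaling to equal sums). A difference in timing at harvest and a slower maturation of HBBko cells could each account for the shares of called genes, and the explanation stays open.

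The values below were singled out because the HBBko against WT difference itself differed between stages by the interaction test, in log2 with its adjusted p. Groups of 3 are too small for a test of single deviating libraries. From undifferentiated to 48 h the differences were HBD -1.38 (0.00030), HBE1 0.70 (0.012; 0.29 with a pseudocount of 0.1), INHBE 2.27 (0.00052), DBN1 1.59 (0.0022), RHOB -1.98 (7.9e-05), CALB2 -1.92 (2.2e-07) and TTC39A -1.38 (0.00013). ATF4 was at 0.41 (0.0499), a call lost with a pseudocount of 0.1 (0.059), no filter (0.13), median-of-ratios scaling (0.081) and a fit of only these groups (0.087). Single libraries also ended the ATF4 call: undifferentiated WT replicate 3 (0.051), WT 48 h replicates 1 and 2 (0.11 and 0.098), undifferentiated HBBko replicates 1, 2 and 3 (0.077, 0.11 and 0.066), and HBBko 48 h replicates 1, 2 and 3 (0.094, 0.09 and 0.09). MT1X was at 1.98 (0.026), lost with no filter (0.085), in a fit of only these groups (0.059) and without WT 48 h replicate 2 (0.054) or 3 (0.054) or HBBko 48 h replicate 1 (0.060) or 3 (0.054). MT1G was at 1.72 (0.025), lost with no filter (0.082) and without WT 48 h replicate 3 (0.056), undifferentiated HBBko replicate 2 (0.056) or HBBko 48 h replicate 1 (0.053), 2 (0.050) or 3 (0.052). MT2A was at 1.61 (0.023), lost with no filter (0.074) and without undifferentiated HBBko replicate 2 (0.051) or HBBko 48 h replicate 1 (0.057). ACTG1 was at -1.81 (0.023), lost with no filter (0.076) and without WT 48 h replicate 3 (0.051), undifferentiated HBBko replicate 1 (0.053) or 3 (0.057), or HBBko 48 h replicate 3 (0.058).

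From undifferentiated to 5 d the differences were HBB -0.97 (0.0038), HBG1 2.37 (1.5e-06), HBG2 2.68 (2.2e-06), HBE1 1.99 (1.9e-07), ATF4 0.96 (2.7e-05), BCL11A -0.52 (0.0022), TSPAN32 2.52 (7.4e-08), CHAC1 2.40 (5.3e-05), NEIL1 2.32 (8.7e-08), HMOX1 -3.22 (3.3e-08), EGR1 -2.58 (5.5e-07), EYA4 -2.53 (8.3e-09) and TMSB4X -2.42 (1.2e-07). From 48 h to 5 d they were HBG1 1.70 (9.0e-05), HBG2 1.91 (0.00013), HBD 1.17 (0.00016), HBE1 1.29 (2.9e-05), ATF4 0.55 (0.0058), HIST1H1C 2.56 (3.6e-07), FTCD 1.93 (1.6e-05), HBZ 1.76 (1.5e-05), HMOX1 -4.03 (1.6e-08), CDKN1A -2.74 (4.1e-07), MT2A -2.27 (0.00099) and MT1G -2.27 (0.0021). HBB from undifferentiated to 5 d was lost with no filter (0.070), and BCL11A with rescaling to equal sums (0.096).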

How the results depend on the processing

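Rescaling to equal sums was the test chosen only after the results were seen; every other alternative was planned. Of 21241 named gene values under alternatives, 20419 counted as the same, 772 became weaker, 40 stronger and 10 reversed. Same means on the same side of the threshold, with the same direction or, where called in neither fit, in either direction. Reversed means a change of direction in a value called in the main fit or under the alternative. List tests were counted in the same way, by the direction that the list test gave. Between the lines, 39 of 87 list tests were called; an estimated correlation ended all 39, fry left 62 as they were with 24 stronger and 1 reversed, rescaling to equal sums left 74 with 5 weaker, 7 stronger and 1 reversed, and globins removed, median-of-ratios scaling and the block left 86 each with 1 stronger. Without 1 library at a time 505 of 522 list tests stayed, 3 became weaker and 14 stronger. The block on the replicate number, used because the numbers pair some groups, moved no count of calls by over 1.5 times and among named genes and lists changed no call but heme synthesis in undifferentiated cells, HBG1 (0.67) and HBG2 (0.77) from undifferentiated to 48 h, and core histones in WT at 48 h (median 0.19, adjusted p = 0.053). The gamma-globin share difference kept its direction with either HBG gene or another denominator (39.8 points at 5 d, 37.1 with HBG2 alone, 2.78 with HBG1 alone and 40.0 over HBB, HBG1 and HBG2). The depth of the libraries is unknown, so how far it limits genes at low values cannot be given.

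A fit of only the groups compared called 2882 genes in undifferentiated cells (main 5197) and 4275 at 48 h (main 2249). Which of these 2 stages had more called genes therefore depends on the fit. The main fit shares 1 spread per gene over the 6 groups, and the smaller fits use only that of the groups compared. The median SD of a gene on the log2 scale was 0.150 in undifferentiated WT and 0.0696 in undifferentiated HBBko. At 48 h it was 0.0679 in WT and 0.0490 in HBBko. At 48 h library weights gave 5189, rescaling to equal sums 4191 and single libraries left out 1179 to 1759. From undifferentiated to 48 h the interaction count was 830 to 2481 with single libraries left out (main 1582), and from 48 h to 5 d it was 4682 with library weights (main 2958). Genes called in 1 direction at all 3 stages (main 918) were 1487 with rescaling to equal sums and 592 to 1125 with single libraries left out. The cause of the other changes was not tested.

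Quantile normalization reversed HBA1 and HBA2 at 48 h (0.60 and 0.42) and the HBB interaction from undifferentiated to 48 h (1.73) and to 5 d (1.73). It gives each rank within a library 1 fixed value. From the highest, the order was HBB, HBA1, HBA2 in every WT library at 48 h and 5 d. In HBBko libraries of these stages it was HBA1, HBA2, HBB. The quantile values of these genes therefore follow their ranks and not the amount of signal. Rescaling to equal sums reversed ATF4 (0.33), MYB (0.0675), EIF2AK1 (0.0137) and E2F2 (0.0098) between the lines at 5 d. Of these, ATF4 was called only after rescaling (adjusted p = 0.00080). MYB, EIF2AK1 and E2F2 were called only before it and lay near 0 after it (adjusted p = 0.48, 0.84 and 0.93). Rescaling multiplies every gene of a library by the same factor. Library sums at 5 d were 1456800 to 1508340 in WT and 1152840 to 1183460 in HBBko. Mean HBB was 439258 scaled TPM in WT and 70806 in HBBko. The median over all tested genes moved from 0.02 to 0.27. The reversals of these genes at 5 d therefore follow a shift shared by all genes. The same rescaling also reversed HIST1H1C in WT at 5 d (-0.0162, no longer called, adjusted p = 0.90). It reversed the EIF2AK1 interaction from undifferentiated to 5 d as well (0.20, adjusted p = 0.028). Ribosomal proteins at 48 h were reversed as well (median 0.14). Fry and camera gave opposite directions for the fetal and neonatal programme between the lines at 5 d (median -0.25), in WT at 48 h for eIF2alpha kinases and phosphatase (-0.0396), the interferon response (-0.18) and megakaryocyte markers (0.16), in WT at 5 d and HBBko at 48 h for megakaryocyte markers (-0.19 and 0.17), and in HBBko at 5 d for the interferon response (0.16). The cause of the opposite directions of fry and camera was not tested.

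Counts of genes at least 2-fold apart moved with the pseudocount, since it pulls genes at low values toward 0: with 0.1 and 5 they were 464 and 63 in undifferentiated cells (main 198), 278 and 28 at 48 h (main 110), and 798 and 155 at 5 d (main 417). With a pseudocount of 5 they were 715 and 2999 in WT (main 1475 and 4813) and 705 and 3017 in HBBko (main 1474 and 4773) at 48 h and 5 d. For interactions they were 147 and 17 from undifferentiated to 48 h (main 69, and 44 with a filter of 5), 1027 and 149 to 5 d (main 506), and 471 and 72 from 48 h to 5 d (main 233).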

Other observations

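The tests of these genes were planned, and the choice of genes by opposite directions was made only after the results were seen.

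Some genes moved in opposite directions before and after differentiation. HSPA5, the main chaperone of the endoplasmic reticulum, was 125 ± 6.80 scaled TPM in undifferentiated HBBko cells against 59.5 ± 2.23 in WT (SD, n = 3, log2 fold change 1.05) and 76.6 ± 6.61 against 169 ± 7.10 at 5 d (-1.13). The transcription factor OSR2 went from 1.09 to -1.18, the immediate early gene EGR1 from 1.49 to -1.09, the glycolytic enzyme PFKP from 0.76 to -0.78 and UBASH3B from 1.00 to -1.09 between the same stages. The DNA glycosylase NEIL1 went the other way, from -0.82 to 1.502. HMOX1 was higher in HBBko at 48 h (1.22) and lower at 5 d (-2.81), and CDKN1A followed (0.86 and -1.88).

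Beside the globins, the 38 genes that kept a 2-fold difference at every stage include metabolic enzymes and regulators of several kinds. Lower in HBBko were the enzymes GPT2 (-2.08, -1.82 and -1.45 at the 3 stages) and PCK2 (-1.30, -1.09 and -1.15). The chromatin organizer SATB1 (-1.37, -1.30 and -1.45), the homeobox factor PITX1 (-1.04, -2.28 and -2.15) and the integrin ITGA5 (-2.00, -1.15 and -1.61) were lower as well. Higher were CAPN2 (1.01, 1.19 and 1.24), BEX1 (1.18, 1.06 and 1.38) and TMEM161B (1.06, 1.09 and 1.79). The pseudogene HBBP1, in the same cluster as HBB, rose to 1013 ± 61.1 scaled TPM in HBBko at 5 d against 117 ± 12.2 in WT (3.10).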
